A study of Mus musculus with 2 samples.

How the data were processed

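In situ Hi-C was done on 2 biological replicates of sorted mouse olfactory sensory neurons that express the odorant receptor gene Olfr1507. Per the labels, the replicates held 170000 and 220000 cells, were fixed with 1% formaldehyde and digested with DpnII, and came from the olfactory epithelium of adult 129P2/OlaHsd mice of mixed sex that carry a MOR28-GFP allele. Sorting was by GFP fluorescence. The labels list no treatment.

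Per the series design text, the authors mapped the reads to GRCm38, combined the contacts of both replicates into 1 matrix and called boundaries from that matrix. The deposited boundary list gives a chromosome, an interval of 5000 bp, a class (strong or weak) and a strength for each boundary. The deposited strength is a score whose scale is not given in the sources used here. Checked on the list, the lowest score lies at 0.2 and the class changes from weak to strong at 0.5. The strength of a boundary is the authors' own value and was used only within the list, to describe, rank and filter boundaries and to compare boundaries with and without a TSS or a motif match. The boundary caller, its version, its window size, the aligner and the filters on read pairs are not given in the sources used here. Insulation and compartment tracks named in the design text were not used here, nor were contact matrices or reads.

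The replicates cannot be separated in the list, so no value has a replicate error, and no replicate could be left out. The number of read pairs behind each boundary is unknown, since the list holds no counts. The smallest domains a map can show depend on its depth and its bin size, so the number of boundaries and their spacing are properties of this map. Intervals given for shares of boundaries are 95% Wilson intervals, those for differences of shares are Newcombe intervals and the one for the median spacing comes from the binomial distribution. They cover counting error only. Boundaries and genes are not biological replicates, and neighbouring ones are not independent.

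Coordinates were joined to the GRCm38 sequence and a GENCODE gene annotation of the same build. All boundaries lay within the assembled spans of chromosomes 1 to 19 and X. The reference sequence is of another strain than the mice, so strain differences in sequence were not covered. The transcription start site (TSS) of a gene was the 5′ end of its annotated gene model, and 21755 protein-coding genes were used. A TSS or motif was counted at a boundary when it lay in the boundary interval widened by 10 kb on each side. CTCF motif matches were occurrences of CCASYAGRKGGC, written in IUPAC codes, on either strand, and the reversed but not complemented pattern CGGKRGAYSACC was the control.

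Each count was compared with 100000 draws in which all boundaries of a chromosome were shifted together by a random circular offset within its assembled span. The shifts keep the spacing of boundaries and the clustering of gene families, and each permutation p is two-sided. The smallest p these draws can give is 1e-05, and values printed as 1e-05 are at that limit. For the gene lists, p was adjusted by Benjamini and Hochberg over 21 lists, with 0.05 as the threshold. Fisher's exact test, two-sided, served for strong against weak boundaries and for motif strand. Mean strengths were compared by a two-sided permutation test with 100000 resamples.

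Odorant receptor clusters were runs of at least 5 protein-coding odorant receptor genes less than 500 kb apart. Cluster edges were the outermost gene ends, and an edge was counted at a boundary when a boundary midpoint lay within 50 kb. The 21 lists covered genes of mature and immature olfactory sensory neurons, their regulators, basal, sustentacular and other cells of the mucosa, clustered gene families, and 4 sets of widely expressed genes. The gene lists, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. Named genes followed a rule set at the same time. The rule took Olfr1507 and the genes in its interval, up to 3 members per list at the strongest boundaries, the nearest protein-coding TSS of the 10 strongest boundaries, and the first and last gene of the 10 odorant receptor clusters with most genes.

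Mappability was approximated by the share of 32-base sequences, sampled every 250 bp, that occur once in the genome. This share was averaged over 21 neighbouring bins when bins were matched. The alternatives were the strong boundaries alone, the 1842 strongest boundaries, merged neighbours, other window widths, all annotated genes, other cluster definitions, a longer motif, 10000 random placements, random protein-coding genes and the autosomes alone. The tests were also tried on simulated data, made by circular shifts of the real boundaries. With nothing planted, 4% of 100 simulations passed 0.05 for TSSs, 8% for the cytosolic ribosomal list and 1% for cluster density. These data are made as the draws of the test are, so low rates follow from the design and do not check the choice of shifts. With 10% of boundaries moved to TSSs, 100% passed. With a boundary added at 20% of the ribosomal list's TSSs 99% passed, and with 30% of the boundaries in clusters removed 92% passed. Power for the shorter lists was not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.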

Results

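Chromatin boundaries were mapped in mature olfactory sensory neurons of the mouse that express Olfr1507, an odorant receptor gene also called MOR28. Each mature olfactory sensory neuron expresses a single odorant receptor gene out of a very large family, and the neurons were sorted for 1 such choice. In situ Hi-C joins and sequences DNA ends that lie close together in fixed nuclei, and a boundary is a position across which few contacts pass, so that it parts neighbouring domains. There was 1 group of 2 biological replicates, which the authors combined before calling boundaries. The data are therefore a single list for 1 cell type, with no replicate error and an unknown depth, and each comparison below sets parts of the genome against one another.

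The neurons' genome was parted by 7367 boundaries on chromosomes 1 to 19 and X. Of these, 4052 were strong (55.0%, 95% Wilson interval 53.9 to 56.1) and 3315 were weak. Boundary strength ranged from 0.20 to 4.26 with a median of 0.563. The median was 0.932 among strong and 0.305 among weak boundaries. Neighbouring boundaries lay a median of 265 kb apart (95% interval 260 to 270), with quartiles of 185 and 405 kb. The shortest of the 7347 spacings was 60 kb and the longest 11680 kb. The spacing is set by which boundaries are counted, with a median of 400 kb between strong boundaries and 895 kb between the 1842 strongest ones.

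The X chromosome had the lowest boundary density of the 20 chromosomes. It held 373 boundaries, or 2.22 per Mb, against 2.92 ± 0.244 per Mb (SD, 19 autosomes), a ratio of 0.762. Among the autosomes, chromosome 11 had the highest density at 3.52 per Mb and chromosome 14 the lowest at 2.41 per Mb. On the X 36.5% of boundaries were strong, against 56.0 ± 2.93% on the autosomes (SD, 19 autosomes), whose range was 50.7 to 61.2%. The ratio was 0.495 for strong boundaries alone and 0.380 for the 1842 strongest boundaries. With 1 X against 19 autosomes an exact permutation cannot give a two-sided p below 0.05, so none was computed. Unique 32-base sequences made up 68.6% of the X and 78.4 to 88.7% of the autosomes, and GC content was 39.3% on the X and 40.5 to 43.8% on the autosomes. With bins matched for GC content and nearby non-receptor TSSs, the X had 0.952 times the expected number of boundaries, within the autosomes' range of 0.863 to 1.09. With bins matched for unique sequence it had 0.844 times, near the lower end of their range of 0.836 to 1.18.

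**Figure D1:**
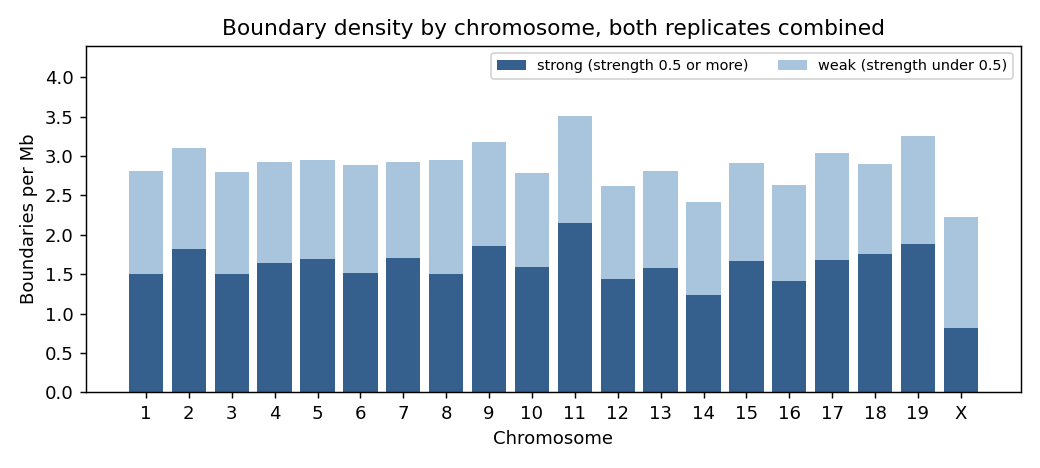
Boundaries per Mb of chromosome span (vertical axis) on each chromosome (horizontal axis), from both replicates combined. The span runs from the first to the last assembled base and includes internal gaps. Strong boundaries are in dark and weak ones in light blue, stacked. The X is lowest at 2.22 per Mb and chromosome 11 highest at 3.52 per Mb.

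Boundaries lay at gene promoters more often than shifted boundaries did, and strong boundaries more often than weak ones. A protein-coding TSS lay in the window of 2145 of the 7367 boundaries (29.1%, 95% Wilson interval 28.1 to 30.2). Circular shifts gave 17.1% (95% of draws 16.3 to 18.0), so the share was 1.70-fold higher (permutation p = 1e-05, the smallest these draws can give). Among strong boundaries 34.0% had a TSS (1376 of 4052), against 23.2% of weak ones (769 of 3315). The difference was 10.8 points (95% Newcombe interval 8.70 to 12.8, odds ratio 1.70, Fisher's exact p = 3.26e-24). Boundaries with a TSS had a mean strength of 0.812 ± 0.530 (SD, n = 2145) against 0.693 ± 0.510 (SD, n = 5222) without. That difference was 0.119 (SE 0.0134, permutation p = 1e-05).

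The 10 strongest boundaries lay near genes of several kinds. The strongest, with a strength of 4.26, was at chromosome 1, 88305001 to 88310000, inside Trpm8, the gene of a cold-activated ion channel. It overlapped exon sequence of that gene, and its midpoint was 29.8 kb from the TSS. The next, with a strength of 3.81, was at chromosome 11, 3195001 to 3200000, in Drg1 and over the pseudogene Fau-ps2. The nearest TSS there was that of Sfi1, at 4.04 kb, and the boundary lay 95 kb from the first assembled base of the chromosome. Others were at Pdcl (strength 3.29), Eif1, a translation initiation factor gene (3.10), AW209491 (2.97) and Trrap (2.94). At Trrap, on chromosome 5 at 144765001 to 144770000, the TSS was 0.232 kb from the midpoint. The boundary nearest to Gm527 had a strength of 3.09 and overlapped no gene, and that at Hyls1 (2.95) overlapped Pate2. The boundary at Zfp984 (2.98) lay in the gene. That nearest to Ccdc90b (3.0) lay inside Dlg2, a gene of a synaptic scaffold protein, with the nearest protein-coding TSS 474 kb away. For 7 of the 10, the TSS was under 10 kb from the midpoint.

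CTCF binds DNA in a given orientation and is known to hold many boundaries, and matches to its motif were concentrated at the boundaries of these neurons. A match lay in the window of 1763 boundaries (23.9%, 95% Wilson interval 23.0 to 24.9), against 11.1% of shifted ones (95% of draws 10.4 to 11.8). The share was 2.15-fold higher (permutation p = 1e-05). The reversed control pattern is rare, with 339 matches in the genome against 12728 for the motif. It lay at 35 boundaries, 0.475% against 0.336% under shifts, which was 1.41-fold higher (permutation p = 0.0377). Boundaries with a motif match had a mean strength of 0.860 ± 0.531 (SD, n = 1763), and those without 0.686 ± 0.508 (SD, n = 5604). The difference was 0.174 (SE 0.0143, permutation p = 1e-05).

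Motif strand changed across the boundary. Within 50 kb to the left of a boundary midpoint, 1046 of 3061 matches were on the forward strand (34.2%), and within 50 kb to the right 1980 of 3072 were (64.5%). The difference was 30.3 points (95% Newcombe interval 27.9 to 32.6, odds ratio 3.49, Fisher's exact p = 4.16e-126). In the 10 kb right of the midpoint there were 76.2 forward and 45.5 reverse matches per 1000 boundaries. In the 10 kb left of it there were 73.3 reverse and 50.4 forward matches per 1000 boundaries. Most matches on the right were forward and most on the left reverse, pointing away from the boundary, while 1092 on the right and 1046 on the left pointed toward it.

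**Figure D2:**
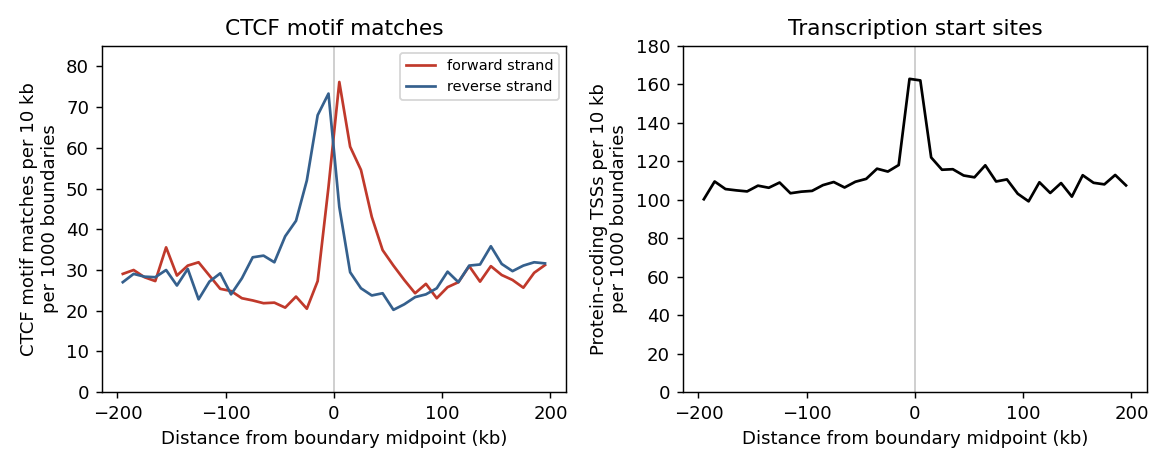
Motif matches (left, forward strand in red and reverse strand in blue) and protein-coding TSSs (right) per 10 kb and per 1000 boundaries, by distance from the boundary midpoint in kb. Forward matches peak at 76.2 just right of the midpoint, reverse matches at 73.3 just left of it, and TSSs at 163 beside it.

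Genes of 4 widely expressed protein complexes had TSSs at boundaries more often than under shifts. They were 29 of 82 cytosolic ribosomal protein genes (35.4% against 7.31%, 4.84-fold, adjusted permutation p = 7.0e-05) and 13 of 39 genes of the proteasome, which degrades proteins (33.3% against 7.36%, 4.53-fold, adjusted permutation p = 7.0e-05). They were also 22 of 89 respiratory chain genes (24.7% against 7.34%, 3.37-fold, adjusted permutation p = 7.0e-05) and 18 of 78 mitochondrial ribosomal protein genes (23.1% against 7.49%, 3.08-fold, adjusted permutation p = 0.000157). The other 17 lists had no call against shifts. The same 4 lists were above random protein-coding genes of the same chromosomes, by 1.75 to 2.74-fold. With the boundary interval alone, without the added 10 kb, the mitochondrial ribosomal list lost its call (2.56-fold, adjusted permutation p = 0.606).

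Rps23, Rps24 and Rps3, of the small ribosomal subunit, lay at boundaries with strengths of 2.83, 2.23 and 1.96. The Rps23 boundary was at chromosome 13, 90915001 to 90920000, 5.46 kb from the TSS, and that of Rps24 at chromosome 14, 24485001 to 24490000, 0.375 kb from it. Among proteasome genes the strongest were Psmd6 (2.57), Psmd7 (2.41) and Psmc1 (2.28), which encode parts of the regulatory particle. Among mitochondrial ribosomal genes they were Mrps27 (1.93), Mrps30 (1.75) and Mrps28 (1.58). The respiratory chain genes were Ndufs1 (2.02) and Ndufb10 (1.52), both of complex I, and a gene model with the symbol Atp5o (1.94). That model spans chromosome 16, 91684398 to 91926982, and its TSS, 91926982, was the one counted among the 22 and may not be that of the ATP synthase gene. The annotation also holds a compact model with this symbol, at 91925214 to 91931687, whose TSS lay 5.81 kb from the midpoint of the same boundary and was in its window too.

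Of the lists for the olfactory sensory neuron itself, none passed the test against shifts. Of 25 mature neuron genes, 2 were at boundaries (8.0% against 7.22%, adjusted permutation p = 1). They were Gng13, a G protein subunit gene of the odorant transduction cascade (1.21), and Umodl1 (0.705). Of 24 transcription and chromatin regulators, 4 were (16.7% against 7.40%, adjusted permutation p = 0.258). These were Ebf3, a transcription factor gene (2.5, chromosome 7, 137320001 to 137325000), Emx2, a homeobox gene (2.33, chromosome 19, 59445001 to 59450000), Lhx2 (weak, 0.447) and Atf5 (weak, 0.359), the last named after its value was seen. Of the 15 immature neuron genes 0 were at boundaries against 7.10% under shifts (adjusted permutation p = 0.588).

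Lists for the other cells of the mucosa also had no call. Of 12 basal progenitor and cell cycle genes, 2 were at boundaries, Pcna (0.844) and Aurkb (0.729), against 7.52% under shifts (adjusted permutation p = 0.414). None of 11 sustentacular and none of 8 horizontal basal cell genes was (adjusted permutation p = 0.741 for both). Of 22 genes of other mucosal cells, 4 were (18.2%, adjusted permutation p = 0.258), among them the macrophage genes Cd68 (0.940) and C1qa (0.85) and the glial gene Sox10 (0.770).

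Several clustered gene families had shares below those under shifts, with no call. Odorant receptor genes were at boundaries in 67 of 1134 cases (5.91% against 7.56%, 0.782-fold, permutation p = 0.0743, adjusted 0.258), with Olfr1423 (2.84), Olfr220 (2.78) and Olfr543 (2.53) at the strongest. Vomeronasal receptor genes were in 18 of 328 cases (5.49%, adjusted permutation p = 0.414), led by Vmn1r30 (1.70), Vmn1r179 (1.66) and Vmn1r188 (1.65). None of the 15 trace amine receptor genes (adjusted permutation p = 0.741) and none of the 56 clustered protocadherin genes (adjusted permutation p = 0.414) was at a boundary. Of 53 keratin genes only Krt84 was, at a weak boundary (0.450, adjusted permutation p = 0.376). Random protein-coding genes of the same chromosomes gave another reference, which treats the neighbouring genes of a cluster as independent. Against it 5 families were lower with an adjusted p under 0.05, and none of them had a call under the shifts, which keep the clustering. These were odorant receptors (0.461-fold), vomeronasal receptors (0.459-fold), zinc finger genes (0.695-fold), keratins (0.125-fold) and protocadherins, with 0 members at boundaries.

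The remaining families had shares above or near those under shifts, again with no call. Of 394 zinc finger genes, 35 were at boundaries (8.88% against 7.39%, adjusted permutation p = 0.444), with Zfp984 (2.98), Zfp202 (2.59) and Zfp407 (2.53) at the strongest. Of 67 replication-dependent histone genes, 11 were (16.4%, adjusted permutation p = 0.258), and Hist1h1a, Hist1h3a and Hist1h4a shared 1 boundary with a strength of 1.96. Of 100 cytochrome P450 genes, 11 were (11%, adjusted permutation p = 0.414), among them Cyp2f2 (2.25), Cyp2d26 (1.83) and Cyp4f15 (1.74). Hoxd13, Hoxd12 and Hoxd11, at 1 boundary with a strength of 1.22, were the 3 of 39 Hox genes (7.69%, adjusted permutation p = 1). H2-Ke6 (0.769), H2-Ob (0.364) and H2-M3 (0.301) were the 3 of 34 genes named for the major histocompatibility complex (8.82%, adjusted permutation p = 1).

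**Figure D3:**
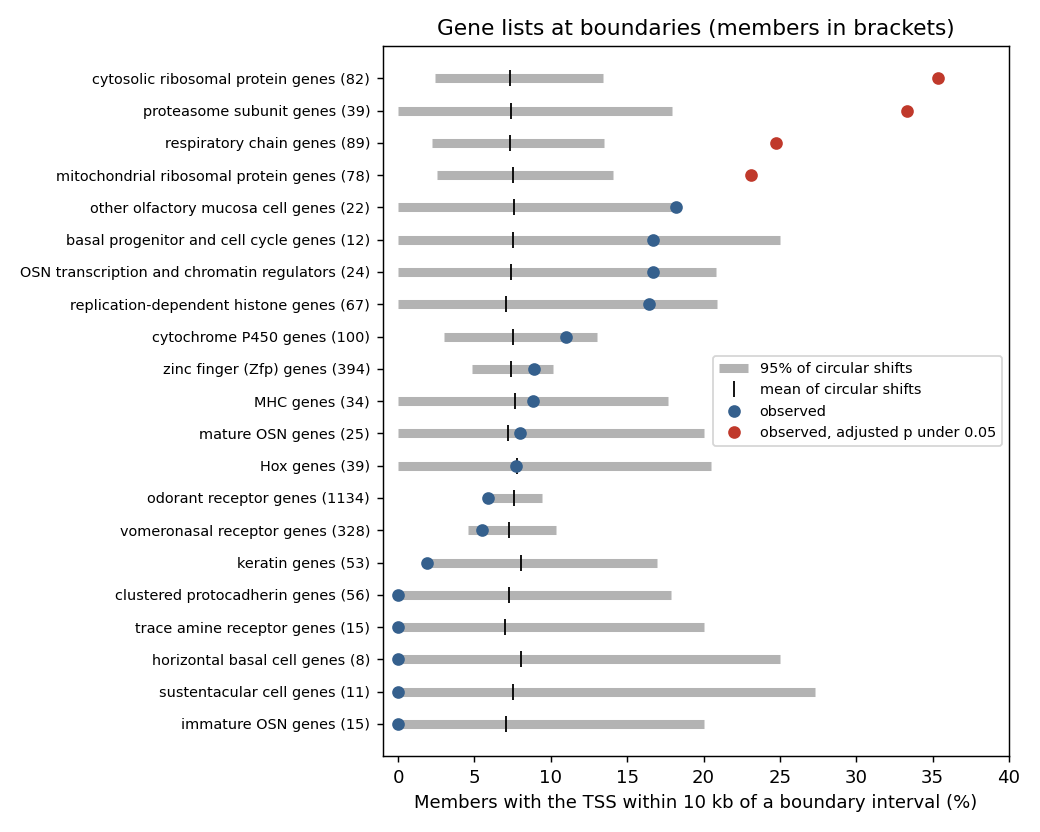
Percent of each list's genes whose TSS lay at a boundary (points), with the mean (tick) and 95% range (grey bar) of circular shifts; list sizes are in brackets. The 4 lists in red, from 23.1% to 35.4%, lie above the range of shifts with an adjusted p under 0.05.

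Odorant receptor gene clusters held fewer boundaries than shifted boundaries gave, and their edges lay near boundaries more often. The 33 clusters, with 1092 genes in 30.42 Mb, held 64 boundaries, 27 strong and 37 weak. Shifts gave 91.3 (95% of draws 75 to 108), so the count was 0.701-fold (permutation p = 0.001). The density was 2.10 per Mb inside clusters and 2.87 per Mb outside. Of the 66 cluster edges, 38 had a boundary midpoint within 50 kb (57.6%), against 29.4% under shifts (95% of draws 18.2 to 40.9), which was 1.96-fold higher (permutation p = 1e-05). Both edges were near a boundary in 10 clusters and 1 edge in 18. With the strong boundaries alone the density in clusters was 0.518-fold (permutation p = 0.00044). With the 1842 strongest boundaries alone it was 0.648-fold and no longer past the threshold (permutation p = 0.0734). Unique 32-base sequences made up 73.6% of the clusters and 83.6% of the rest, and GC content was 39.0% and 41.8%. Against bins outside clusters matched for GC content and the number of non-receptor TSSs nearby, the clusters held 64 boundaries against 67.1, a ratio of 0.954 that was not past the threshold (permutation p = 0.591). Against bins matched for unique sequence the ratio was 0.814 (permutation p = 0.00974). The cluster edges were not matched for GC content, nearby TSSs or unique sequence.

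Of the 10 clusters with most genes, 8 lay below the mean density of their chromosome. The largest, from Olfr987 to Olfr1274-ps on chromosome 2 (85330779 to 90403897), had 227 genes and 8 boundaries, against 15.8 at the density of chromosome 2. Only 1 of those 8 was strong. The cluster from Olfr160 to Olfr986 on chromosome 9 (37708964 to 40190134, 95 genes) had 4 boundaries, all weak, against 7.88. That from Olfr1417 to Olfr1505 on chromosome 19 (66 genes) had 5 against 6.82, and that from Olfr20 to Olfr412 on chromosome 11 (30 genes) had 1 against 3.57. The cluster from Olfr1275 to Olfr1318 on chromosome 2 (39 genes) had 1 against 2.89, and that from Olfr467 to Olfr519 on chromosome 7 (42 genes) had 2 against 3.17. The other 4 were close to the chromosome's density. Olfr543 to Olfr692 on chromosome 7 (102476579 to 105369355, 129 genes) had 8 against 8.47, Olfr9 to Olfr827 on chromosome 10 (60 genes) 4 against 3.41, Olfr90 to Olfr136 on chromosome 17 (49 genes) 4 against 3.80, and Olfr24 to Olfr18 on chromosome 9 (37 genes) 5 against 5.03. Odorant receptor genes lay in intervals with a median length of 560 kb (quartiles 330 and 790, 1134 genes), and other protein-coding genes in intervals of 275 kb (quartiles 195 and 395, 20404 genes). Each gene was counted, so an interval with many genes counts many times, and the genes are not independent values.

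**Figure D4:**
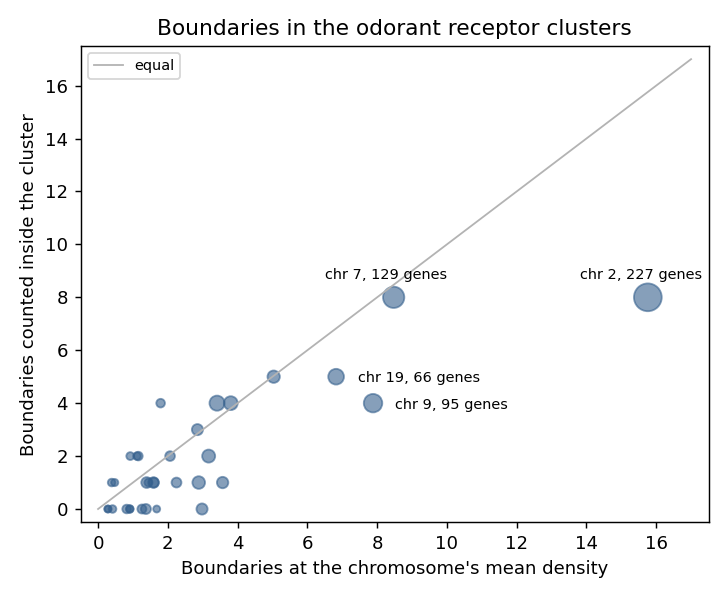
Boundaries counted inside each of the 33 odorant receptor clusters (vertical axis) against the number that its length would hold at its chromosome's mean density (horizontal axis); point area grows with the number of genes and the line marks equality. The cluster on chromosome 2 with 227 genes has 8 boundaries against 15.8.

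Olfr1507, the receptor gene expressed in the sorted neurons, lay in 1 of the longest boundary-free intervals of the genome. The gene is at chromosome 14, 52488791 to 52495749, on the reverse strand, at the end of a cluster of 8 receptor genes that begins with Olfr221. Its interval was 1685 kb long, at the 99.6th percentile of the 7347 intervals. Among intervals between strong boundaries alone it was the same 1685 kb, at the 93.8th percentile of 4032. To the left the interval was closed by a strong boundary at 52350001 to 52355000, with a strength of 1.92, which overlapped exon sequence of Olfr1513 and lay 143 kb from the Olfr1507 TSS. To the right it was closed by a boundary at 54035001 to 54040000, just past the strong threshold with a strength of 0.518, which overlapped no exon and lay 1542 kb from the TSS.

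The interval held 7 protein-coding genes, all odorant receptor genes at its left end, namely Olfr1513, Olfr1512, Olfr1511, Olfr1510, Olfr1509, Olfr1508 and Olfr1507. The eighth gene of the cluster, Olfr221, lay apart, at a weak boundary (52030001 to 52035000, strength 0.485) that overlapped its exon sequence. From Trav1, between Olfr1510 and Olfr1509, to Trdv3 at its right end, the interval held 113 annotated V segments of the T cell receptor alpha and delta genes and 21 V pseudogenes. These segments are recombined in T cells, not in neurons. Unique 32-base sequences made up 41.1% of the interval, against a median of 86.8% for windows as long. The mice are of another strain than the reference, and differences in copy number between strains over these repeated segments and the receptor clusters were not examined. The intervals rest on the combined map, so no error between replicates can be given for them.

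**Figure D5:**
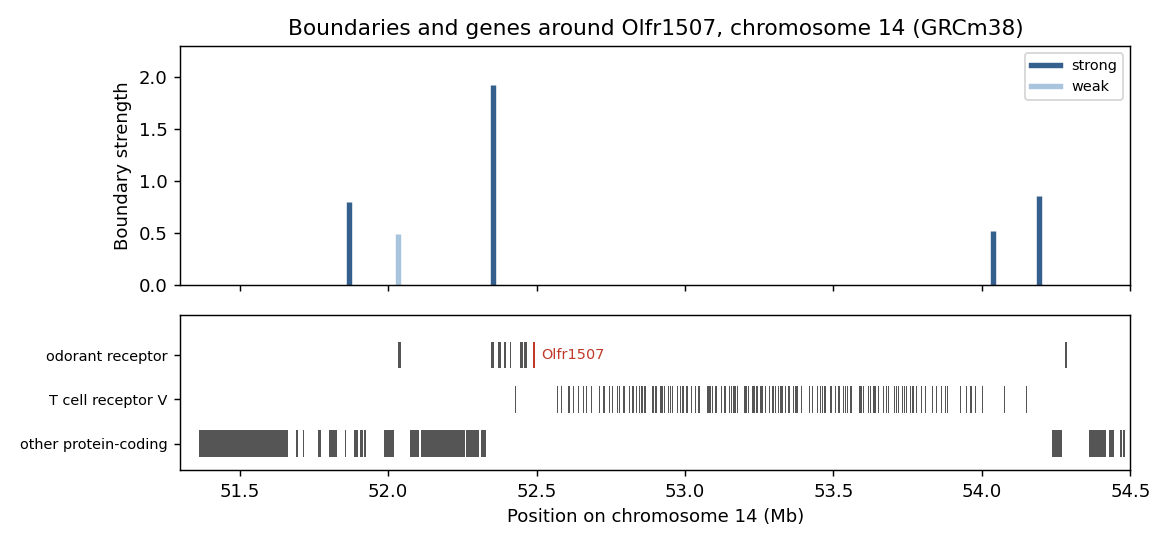
Strength of each boundary (upper panel, dark for strong and light for weak) and annotated genes (lower panel) by position in Mb on chromosome 14 of GRCm38. Olfr1507, in red, lies 143 kb right of the boundary with a strength of 1.92, and no boundary was called over the T cell receptor V segments up to the one with a strength of 0.518.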

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

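The merging of boundaries under 100 kb apart, the inclusion of receptor pseudogenes, the removal of the largest receptor cluster and the other gene model of symbols with several were tests chosen only after the results were seen; without that cluster the density inside clusters was 0.742-fold. Of 75 alternatives to the main comparisons, 67 kept direction and call, stayed within the error or, for the number of lists with a call, stayed near the main count of 4. That number was 3 with the boundary interval alone and 5 with 25 kb added. TSSs at boundaries ranged from 1.31 to 2.24-fold, motif matches from 1.79 to 2.84-fold, the strand odds ratio from 3.49 to 5.50, and cluster edges from 1.44 to 4.44-fold. The difference in mean strength with a TSS ranged from 0.0493 with the boundary interval alone (permutation p = 0.0199) to 0.182 with 25 kb added. That with a motif match ranged from 0.125 to 0.203. Density inside receptor clusters ranged from 0.518 to 0.753-fold and was past the threshold except with the 1842 strongest boundaries (0.648-fold, permutation p = 0.0734), where fewer boundaries were counted. By construction the strong class alone and the strongest part of the list left 4052 and 1842 boundaries with median spacings of 400 and 895 kb. The X to autosome ratio then fell to 0.495 and 0.380, and the cause was not tested. Against random protein-coding genes 9 lists had a call, 4 above and 5 below. That reference counts genes, of which 13.0% lay at boundaries, and ignores their clustering.

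List folds that crossed 1 belonged to lists without a call, and the cause was not tested. They were Hox genes 1.72 and MHC genes 0.70 with strong boundaries. With the 1842 strongest they were Hox genes 3.87, and MHC, basal progenitor and other mucosal genes 0. With the boundary interval alone they were Hox genes 1.65, zinc finger genes 0.688, and mature neuron, regulator, basal progenitor, other mucosal and MHC genes 0. They were Hox genes 1.02 with random placement. Against random genes they were mature neuron genes 0.640, MHC genes 0.656, P450 genes 0.833 and zinc finger genes 0.695, the last with an adjusted permutation p of 0.0486. Of the other 150 list values 144 kept direction and call, 5 gained a call, among them vomeronasal receptor genes with 25 kb added (0.590-fold, adjusted permutation p = 0.0228), and 1 lost it. Over all settings the fold ranged from 2.74 to 8.54 for the cytosolic ribosomal list and from 2.51 to 9.54 for the proteasome list. It ranged from 1.89 to 6.12 for respiratory chain genes and from 1.75 to 5.33 for the mitochondrial ribosomal list. Merging under 50 kb moved nothing, since no spacing is under 60 kb. Depth is unknown, so weak boundaries that were missed cannot be counted, and no replicate could be left out of a combined map.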

Other observations

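The strong share of the X as a test of coverage, the counts by gene type, the longest intervals, the gene families other than vomeronasal receptors and zinc finger genes, the interval from separate windows, and the antigen receptor clusters without that of the Olfr1507 interval, were tests chosen only after the results were seen.

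Of 16 gene types, 6 were at boundaries more often than under shifts, 1 less often, and 9 had no call, among them snoRNA, snRNA and rRNA genes. Of 2196 microRNA genes, 279 had their 5′ end at a boundary (12.7% against 7.23% under shifts, 1.76-fold, adjusted permutation p = 4.0e-05). Protein-coding genes had a like share (13.0%, 1.78-fold), as had processed transcripts (13.7%, 1.86-fold, adjusted permutation p = 4.0e-05 for both). Whether the microRNA genes lay in or beside protein-coding genes was not examined. Antisense transcripts were 1.40-fold and lincRNA genes 1.18-fold higher (adjusted permutation p = 4.0e-05 and 0.00179). Processed pseudogenes, which arise by reverse transcription, were 1.12-fold higher, and unprocessed pseudogenes, which arise by gene duplication, were 0.747-fold (adjusted permutation p = 0.00749 and 0.0128). Of the 12 longest intervals, 11 had less than 30% unique 32-base sequence. The longest, 11.68 Mb on the X (24137500 to 35817500), had 7.23% unique 32-base sequences and 14.8% unknown bases. It held 47 protein-coding genes, Slx among them. The third, 3.595 Mb on chromosome 7, held vomeronasal receptor genes and had 8.17% unique sequence. An exception was 2.96 Mb on chromosome 14 (93917500 to 96877500), with 83.9% unique sequence and 2 protein-coding genes, 4921530L21Rik and Klhl1.

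Odorant receptor clusters held 64 boundaries, against 91.3 under shifts. When the expected number was taken from bins outside clusters with the same share of unique sequence, the ratio of observed to expected was 0.814 (95% of shifted masks 0.866 to 1.21, permutation p = 0.00974), which argues against low mappability as the whole cause. When it was taken from bins with the same GC content and number of non-receptor TSSs nearby, the ratio was 0.954 (95% of shifted masks 0.851 to 1.13, permutation p = 0.591). For strong and weak boundaries together, base composition and the number of non-receptor TSSs nearby may therefore account for the lower density. The tests do not part the one from the other. The receptor genes themselves were not counted, so this match is not one for the gene density of the clusters. Strong boundaries alone had 0.518-fold the density under shifts (permutation p = 0.00044), and neither match was made for them. Whether either would account for that larger deficit was not tested. No biological explanation was tested, since the design holds no other cell type.

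The X had 0.762 times the autosomal boundary density. Matched for unique sequence, its ratio of observed to expected was 0.844, inside the range of the autosomes (0.836 to 1.18) but near its lower end. Matched for GC content and the number of non-receptor TSSs nearby the ratio was 0.952 (autosomes 0.863 to 1.09). For strong and weak boundaries together, both explanations may thus hold and neither is excluded. Strong boundaries alone were at 0.810 per Mb on the X against 1.64 on the autosomes, a ratio of 0.495. They were not matched in either way, so their larger deficit was not tested. The low share of strong boundaries on the X, 36.5%, would go with lower coverage of a single X in male cells. It cannot be told apart from other causes, since the list gives no coverage and the sexes were mixed, and no biological explanation was tested.

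The interval that holds Olfr1507 had no boundary over 1685 kb. Its GC content was 41.1%, near the median of 41.5% for windows as long. Of windows as long with a GC content within 1 point, 1.42% had no boundary. Of 566 such windows that did not overlap, 5 had none (95% exact interval 0.287 to 2.05%). Since such windows are common, their share had to lie near the 0.898% of all windows. The ordinary GC content of the interval itself argues against base composition. All protein-coding genes in the interval were odorant receptor genes. Windows were not matched for the number of non-receptor TSSs, so a role of their absence was not tested. Of 1083 overlapping windows with a unique share within 2 points, 0.0923% had none, below the bound of 5% set beforehand. That share is the Olfr1507 interval itself, which was not left out, so no other matched window lacked a boundary. These windows overlap, however, and only 33 are separate. The Olfr1507 interval was not among the 33, because a matched window that overlaps it was kept instead. Such an overlapping window must hold a flanking boundary, so the result at this place was fixed. None of the 33 lacked a boundary, which allows up to 10.6%. A role of the repeated sequence of the V segments thus stays open and cannot be told apart from chance. Such windows held a mean of 2.19 boundaries against 4.86 for all windows, and neither a difference in copy number between the strain and the reference nor a biological explanation was tested.

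A hypothesis was that a low boundary density is common to clustered gene families. Vomeronasal receptor clusters had 42 boundaries against 66.9 (0.628-fold, adjusted permutation p = 0.00395 over 7 families), but zinc finger clusters had 42 against 41.1. The higher of both folds was 1.02, so the hypothesis as stated was not borne out. Clusters of antigen receptor V segments had 12 against 22.0 (0.545-fold, adjusted permutation p = 0.0458). Among these 5 clusters was that of the Olfr1507 interval, which had prompted the count. Without it the other 4 had 11 against 17.9 (0.615-fold, unadjusted permutation p = 0.0761), so no call was left. The cytochrome P450, keratin and histone clusters had 0.979, 1.24 and 1.34-fold with no call. Vomeronasal clusters had 49.4% unique sequence, zinc finger clusters 64.4% and P450 clusters 62.3%.

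A further hypothesis was that divergent promoters, with an opposite TSS within 1 kb upstream, mark boundaries beyond single promoters. Of 2364 divergent protein-coding TSSs 17.9% were at boundaries, against 12.4% of the other 19391. The difference was 5.45 points (95% Newcombe interval 3.88 to 7.11, Fisher's exact p = 8.70e-13), and 5.08 points without odorant receptor genes (p = 4.99e-11). Both genes of a divergent protein-coding pair were counted, so the interval and the p are too narrow. Neither shifts nor a match for gene density were used for this comparison, so an effect beyond single promoters was not isolated. Divergent promoters may thus lie at boundaries more often, but gene expression was not measured here, and divergent promoters are often those of widely expressed genes.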
